A study of Dicentrarchus labrax with 24 samples.

How the data were processed

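Liver RNA of adult European sea bass (*Dicentrarchus labrax*) was measured on 24 Agilent 1-colour oligonucleotide arrays, 1 array per fish. The fish belonged to a pair of half-sib families, called G and g in the labels, and were fed for 9 months either a fish diet (FD), made of fish meal and fish oil, or a vegetable diet (VD), made of plant meal and plant oil. The groups held 5 fish of family G on FD, 5 of family G on VD, 8 of family g on FD and 6 of family g on VD. Family, diet and sex were taken from the labels. The study design names separate fish for each array.

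The scanner files hold spot intensities, which per the file headers were read with Agilent Feature Extraction 9.5.1.1. The processed intensity of a spot was already background-subtracted and detrended within its array, per the file headers, and had not been scaled between arrays. The flags for detection above background and for outlier spots were set by the same software. The authors also deposited a table of linear intensity values for the same arrays, whose normalization is not stated in the sources used here. Its column medians ran from 12.4 to 124, and its rank correlation with the processed intensity of the same array ran from 0.971 to 1.00 across spots. Its scale factor between arrays therefore stays unknown, and it served only as an alternative.

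From the scanner files, log2 of the processed intensity minus the 75th percentile of that value over the 38070 non-control probes of the array was computed. Levels below are given on this log2 scale, on which 0 is the array's own 75th percentile. Spots flagged as outliers were set missing, which removed 215 values in 212 tested probes. No spot was saturated. A probe was tested when it was well above background on at least 5 arrays, the size of the smallest group, and 20580 probes (54.06%) met this. The array carries 19035 transcripts with 2 probes of 60 bases each. At least 1 probe was tested for 11440 transcripts and both were tested for 9140.

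The probe names, such as DLPD15450_1, consist of a transcript number and a probe number. The files pair 0 of the probes with a gene name or description, and the gene table used here holds neither probe names nor probe sequences, so no probe could be given a gene. The gene lists and the tests of list shifts planned before the data were examined were therefore not run, and no list member was named. The rule for naming was applied to transcripts in place of genes. Each transcript was represented by its tested probe of highest mean over all 24 arrays, and per comparison the 2 largest rises and the 2 largest falls among those past the threshold are named. The plan allowed 10 of each, and was reduced because probe numbers without genes say little.

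All 24 arrays entered 1 linear model with a mean for each of the 4 groups and a term for sex, fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, which left 19 residual degrees of freedom. The sex term was kept because 5 of 10 fish in family G but 2 of 14 in family g were female. Differences were VD minus FD averaged over both families, VD minus FD within each family, the difference between these (diet by family), family G minus family g averaged over both diets and within each diet, and female minus male. P-values were adjusted over the tested probes with the Benjamini-Hochberg method, and an adjusted p under 0.05 was the threshold. Where only some arrays of a compared group had a named probe well above background, their number is given. The choice of design, tests and most alternatives was made before the data were examined.

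The steps were tested on simulated data made from the real means and spreads of all 20580 tested probes, with 200 probes changed. Noise was drawn independently for each probe and array, unlike in real arrays, so the shares apply to that setting. For the diet difference over both families the model recovered 16.4% of 67 probes changed by 0.6 on the log2 scale, 65.7% of 67 changed by 1 and 93.9% of 66 changed by 2. For the diet by family difference the shares were 1.49%, 10.4% and 54.5%. For the family difference over both diets they were 25.4%, 47.8% and 97.0%, and for sex 11.9%, 46.3% and 93.9%.

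The 75th percentile of the processed intensity ran from 99.9 to 327 between arrays with a median of 182. The share of probes well above background ran from 38.6% to 54.7% with a median of 48.8%. The number of arrays limits the precision of each value. Because this median lay below 50%, the percentile over the 13519 probes well above background on all arrays was added as an alternative scaling after the data were seen. The arrays lay on 9 slides, of which 8 held fish of more than 1 group, and were scanned on 5 days. Slide and scan day were used as blocks, and differences were also taken within single slides and scan days.

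Alternatives chosen beforehand were normexp background correction with an offset of 50, quantile normalization, the deposited table, no filter and a strict filter on dim probes, no sex term, males alone, the replicate number as a block, slide as a block, only the groups compared, an intensity trend with a robust prior, array weights, the mean per transcript, and each array left out in turn. Alternatives added later were the second percentile scaling, slide as a random block, scan day as a block, the arrays' signal level as covariates, normexp with quantile normalization, and leaving out the 3 arrays of slide 9, which holds the array of lowest weight. Replicate numbers name different fish and did not pair the samples.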

Results

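Liver transcripts of 24 European sea bass were measured to compare a diet of fish meal and fish oil (FD) with one in which both were replaced by plant sources (VD), in the half-sib families G and g, which according to the study's title differ in growth on an all-plant diet. Family G contributed 5 fish on FD (2 females) and 5 on VD (3 females). Family g contributed 8 fish on FD (1 female) and 6 on VD (1 female). The share of probes well above background averaged 49.4% ± 3.45 (SD, n = 5) in family G on FD and 48.0% ± 1.61 (SD, n = 5) in family G on VD. It averaged 49.2% ± 3.56 (SD, n = 8) in family g on FD and 47.9% ± 5.34 (SD, n = 6) in family g on VD. Across tested probes, the median correlation between arrays of a group lay between 0.958 and 0.962. The probes carry no gene names in the files, so transcripts are given by probe number and sequence.

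The first comparison asked how the liver transcripts of fish on the plant diet differed from those of fish on the fish diet, over both families. Of 20580 probes tested, 4333 (21.1%) passed the threshold, 2281 higher and 2052 lower on VD. These probes belonged to 2671 transcripts. The difference exceeded 2-fold for 713 of the higher and 537 of the lower probes, and 4-fold for 53 and 26. The median size of the log2 difference among the probes that passed was 0.776. An unadjusted p under 0.05 was reached by 7021 probes, against 1029 expected by chance.

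**Figure D1:**
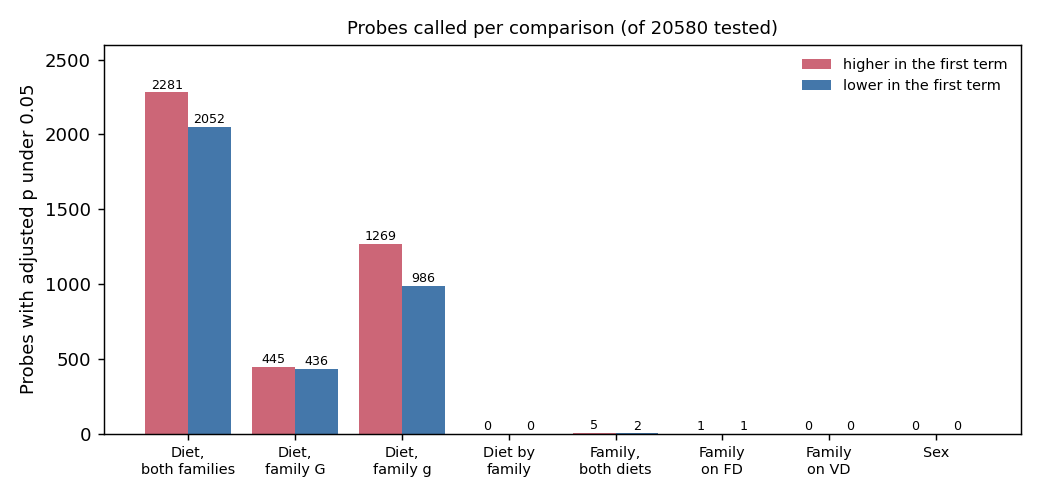
Number of probes with an adjusted p under 0.05 in each comparison (vertical axis, probes), split by direction. Higher means higher on VD for diet, in family G for family, in females for sex, and a larger VD minus FD difference in family G for diet by family. The diet comparison over both families has 2281 higher and 2052 lower probes and the sex comparison has 0.

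The 2 transcripts with the largest rise on VD were measured by DLPD15450_1 and DLPD10402_2. DLPD15450_1 (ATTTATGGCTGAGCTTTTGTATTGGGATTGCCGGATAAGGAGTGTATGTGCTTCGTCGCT, 45% GC) was higher on VD, with a fitted log2 difference of 4.72 ± 0.731 (SE) and a limma adjusted p of 0.000226. Its level was -2.67 ± 1.72 (SD, n = 5) in family G on FD and 1.5 ± 2.14 (SD, n = 5) on VD. In family g it was -3.14 ± 1.78 (SD, n = 8) on FD and 2.08 ± 1.75 (SD, n = 6) on VD. The probe was well above background in 4 of 5 fish of family G and 5 of 8 of family g on FD, and in every fish on VD. With signals below the lowest detected signal of their array raised to it, the FD means were -2.59 and -2.63. The size of the rise depended on the background correction: it was 1.73 with normexp, which ended the call, and 1.78 with normexp and quantile normalization, and limma's adjusted p ran from 6.68e-05 to 0.0805 over the alternatives. The partner probe of the same transcript gave a log2 difference of 4.75, and was also well above background in 4 of 5 and 5 of 8 fish on FD.

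DLPD10402_2 (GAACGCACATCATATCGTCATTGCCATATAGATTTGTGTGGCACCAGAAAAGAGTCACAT, 41.7% GC) was 19.8-fold higher on VD in the fit that allows for sex, with a log2 difference of 4.31 ± 0.901 (SE) and a limma adjusted p of 0.00208. On VD it was among the brighter probes, at 7.66 ± 0.492 (SD, n = 5) in family G and 6.94 ± 1.18 (SD, n = 6) in family g. Fish on FD spread widely, at 3.86 ± 2.23 (SD, n = 5) and 2.72 ± 3.76 (SD, n = 8). The single fish of family g on FD ranged from -2.87 to 6.37. With males alone the difference was 2.87, which ended the call, and limma's adjusted p ran from 0.000566 to 0.143 over the alternatives. Its partner probe gave a log2 difference of 2.97, but was well above background in only 2 of 5 and 2 of 8 fish on FD, and in 5 of 5 and 5 of 6 on VD.

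The 2 transcripts with the largest fall on VD were measured by DLPD09348_1 and DLPD04451_1. DLPD09348_1 (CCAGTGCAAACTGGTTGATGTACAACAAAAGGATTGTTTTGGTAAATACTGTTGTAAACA, 35% GC) was lower on VD, with a fitted log2 difference of -4.87 ± 1.0 (SE) and a limma adjusted p of 0.00183. It stood at 3.82 ± 1.36 (SD, n = 5) on FD and -1.71 ± 2.31 (SD, n = 5) on VD in family G, and at 2.58 ± 2.90 (SD, n = 8) and -1.59 ± 2.80 (SD, n = 6) in family g. On VD it was well above background in 4 of 5 and 4 of 6 fish, and with dim signals raised to the lowest detected one the VD means were -1.35 and -1.32. With normexp the difference was -2.84, and with males alone it was -3.62, which ended the call, as limma's adjusted p ran from 0.000874 to 0.0966 over the alternatives. The partner probe gave -5.01, and was well above background in 4 of 5 and 3 of 6 fish on VD.

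DLPD04451_1 (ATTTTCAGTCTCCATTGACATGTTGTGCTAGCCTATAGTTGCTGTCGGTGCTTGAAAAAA, 40% GC) was 8.79-fold lower, with a log2 difference of -3.14 ± 0.445 (SE) and a limma adjusted p of 0.000116. All 5 fish of family G on VD lay between 0.01 and 2.17, below all 5 on FD, which lay between 3.96 and 5.52. In family g, 5 of 6 fish on VD lay below the lowest fish on FD, at 4.04, and 1 lay above it, at 5.17. The partner probe gave -3.14.

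**Figure D2:**
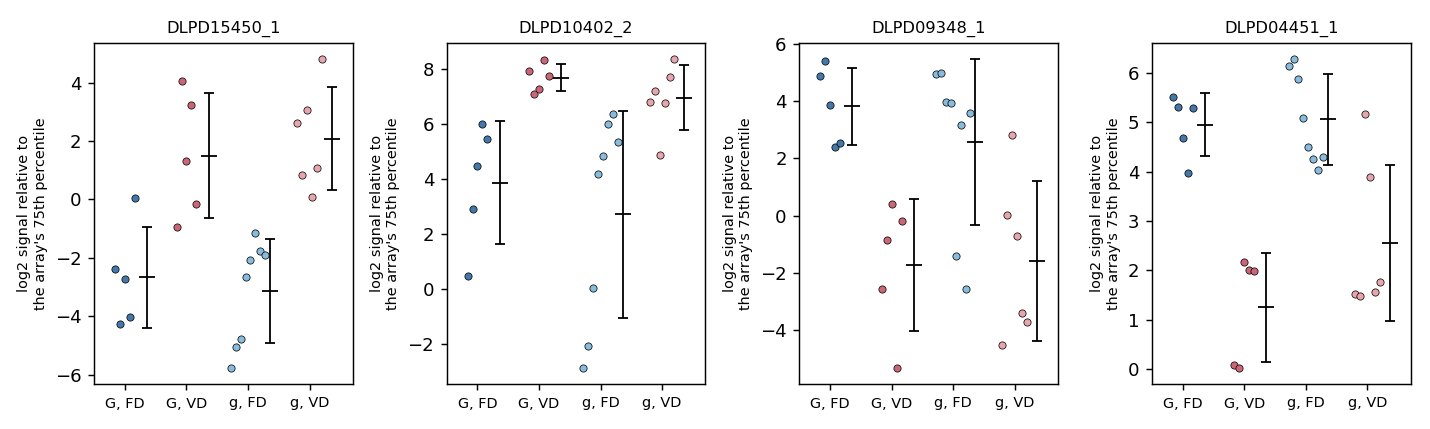
Log2 signal relative to the array's 75th percentile (vertical axis) of the 4 probes with the largest rises and falls on VD, for each group of family and diet (horizontal axis). Points are single fish and bars give the mean and SD. DLPD15450_1 and DLPD10402_2 are higher on VD, and DLPD09348_1 and DLPD04451_1 are lower, in both families.

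The paired probes of a transcript gave a further reading of the same RNA, by other sequences. Among 9140 transcripts with both probes tested, 2382 had at least 1 probe past the threshold, and in 98.95% of these the signs of both were equal. Both probes passed in the same direction for 1660 transcripts, 854 higher and 806 lower on VD, and in opposite directions for 2. Across transcripts the correlation between the diet differences of paired probes was 0.939 (Pearson), with transcripts not being independent replicates. Paired probes read the same fish, so they also follow each other where no probe was called. The correlation was 0.752 for diet by family, 0.732 for family on VD and 0.788 for sex. This agreement therefore speaks for the readings and not for diet as their source. When the probes were ranked by mean level into 4 sets of 5145, 12.6% of the dimmest set passed, and 23.0%, 25.9% and 22.6% of the brighter sets in order.

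The split between rises and falls depended on the scaling. It was 2281 to 2052 (52.6% higher) with the percentile over all probes, 1883 to 2421 (43.8% higher) after quantile normalization, and 1709 to 2725 (38.5% higher) with the percentile over probes well above background on all arrays. Normexp background correction left 35 probes past the threshold, but 4317 passed when quantile normalization followed it. Males alone left 914, while 3441 passed with slide as a block. On the 7 slides that held both diets, between 67.3% and 96.2% of the probes called without that slide had the same sign within it, the lowest on slide 8. Within the 4 scan days with both diets for which it could be computed, the share ran from 67.3% to 96.7%. The lowest came from the same arrays as slide 8.

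Each fish was then placed between the FD and VD means of the other fish of its family, on the probes called without that fish. The mean score was 0.101 ± 0.207 (SD, n = 5) in family G on FD and 0.890 ± 0.299 (SD, n = 5) on VD. It was 0.0677 ± 0.215 (SD, n = 8) in family g on FD and 0.904 ± 0.326 (SD, n = 6) on VD. Of the 24 fish, 22 fell on the side of their own diet. The exceptions were replicate 3 of family G on VD, with a score of 0.408, and replicate 4 of family g on VD, with 0.436.

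**Figure D3:**
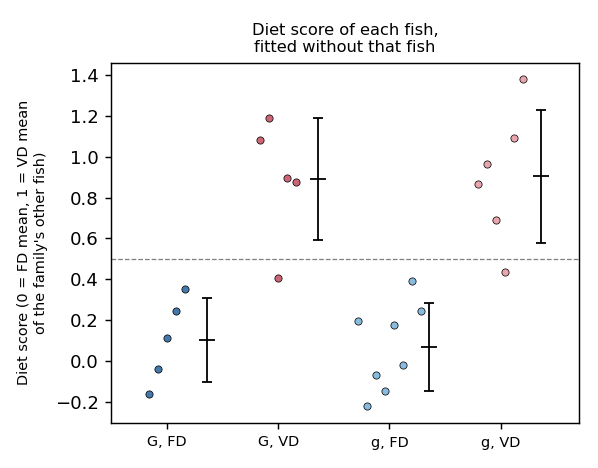
Diet score of each fish, with 0 for the FD mean and 1 for the VD mean of the other fish of its family (vertical axis), by family and diet (horizontal axis). Points are single fish, bars give the mean and SD, and the dashed line marks 0.5. The 13 fish on FD lie between -0.224 and 0.393, and 9 of the 11 fish on VD lie above the line.

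Within family G, 881 probes passed the threshold, 445 higher and 436 lower on VD, from 5 fish against 5. The transcripts with the largest rises were measured by DLPD10072_1 and DLPD15450_1. DLPD10072_1 (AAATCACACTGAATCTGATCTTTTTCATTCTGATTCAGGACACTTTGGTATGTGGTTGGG, 38.3% GC) had means of -1.55 ± 0.665 (SD, n = 5) on FD and 2.79 ± 1.06 (SD, n = 5) on VD. The fitted rise, which allows for sex, was 4.49 ± 1.05 (SE) on the log2 scale, or 22.4-fold, with a limma adjusted p of 0.0241. DLPD15450_1 rose by 4.2 ± 1.11 (SE) on the log2 scale, with a limma adjusted p of 0.0361. The largest falls were those of DLPD09348_1, at -5.57 ± 1.52 (SE) and a limma adjusted p of 0.0403, and DLPD04451_1, at -3.76 ± 0.679 (SE) and a limma adjusted p of 0.0124. With normexp the differences in family G were 2.28 for DLPD10072_1, 1.61 for DLPD15450_1, -2.91 for DLPD09348_1 and -3.01 for DLPD04451_1. The calls of DLPD15450_1 and DLPD09348_1 in family G were each lost in 8 of 18 alternatives and in 6 of 24 fits that left out 1 array, that of DLPD10072_1 in 5 of 18 and 4 of 24, and that of DLPD04451_1 in 3 of 19 and 1 of 24. The count in family G fell to 41 with slide as a block and to 0 without replicate 1 on FD, and was 2150 with array weights.

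Within family g, 2255 probes passed, 1269 higher and 986 lower on VD, from 6 fish against 8. DLPD15450_1 rose, with a fitted log2 difference of 5.23 ± 0.941 (SE) and a limma adjusted p of 0.00299. That size rests in part on the 3 of 8 fish on FD in which it was not well above background, and was 1.86 with normexp. DLPD10372_2 (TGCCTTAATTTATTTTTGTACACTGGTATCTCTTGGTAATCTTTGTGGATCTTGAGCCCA, 36.7% GC) had means of 2.84 ± 3.74 (SD, n = 8) on FD and 7.23 ± 1.09 (SD, n = 6) on VD. The fitted rise, which allows for sex, was 4.48 ± 1.14 (SE) on the log2 scale, or 22.3-fold, with a limma adjusted p of 0.0180, and its partner probe was not tested. Its call was lost in 5 of 19 alternatives and in 1 of 24 fits that left out 1 array, over which the difference ran from 3.63 to 4.89. On FD, replicates 1, 2 and 3 read -3.44, -1.47 and 0.63, and the other fish between 4.49 and 6.04. DLPD09348_1 fell by 4.18 ± 1.29 (SE) on the log2 scale, with a limma adjusted p of 0.0401, a call that was lost in 10 of 18 alternatives and in 9 of 24 fits that left out 1 array. DLPD04152_1 (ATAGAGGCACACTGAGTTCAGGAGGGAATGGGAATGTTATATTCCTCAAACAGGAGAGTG, 45% GC) had a fitted fall of 2.57 ± 0.609 (SE), with a limma adjusted p of 0.0124. It was well above background in all 8 fish of family g on FD, at -1.12 ± 0.877 (SD, n = 8), but in 3 of 6 on VD and 2 of 5 of family G on VD, so the size of the fall is uncertain. With dim signals raised to the lowest detected one the mean of family g on VD was -2.96, and with normexp the difference was -0.779. The count in family g was 935 with slide as a block and 834 without replicate 6 on VD.

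The diet differences of the families were set against each other, since the families share no fish. Probes that passed in both numbered 525, of which 264 were higher and 261 lower on VD, against 27.4 and 20.9 for independent lists. Both lists come from the same fit, with a shared estimate of each probe's spread, so independence is not an exact baseline. The overlap was not permuted. None passed in opposite directions. Of the probes that passed in family g, 92.33% had the same sign in family G, and of those that passed in family G, 97.73% had the same sign in family g. Across all tested probes the differences correlated at 0.555 (Pearson) and 0.545 (Spearman), with probes not being independent replicates. Of 99 permutations of diet within each family, the highest gave 0.503 and the lowest -0.533.

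**Figure D4:**
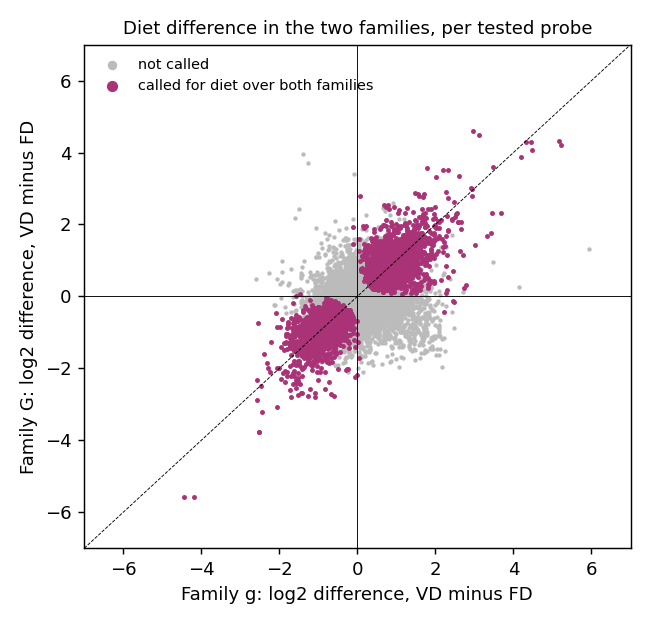
Log2 difference VD minus FD of each tested probe in family g (horizontal axis) and in family G (vertical axis). Purple points are the 4333 probes that passed over both families, grey points are the others, and the dashed line marks equal differences. The purple points lie mostly in the quadrants of equal sign, and the correlation over all 20580 probes is 0.555.

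The test of whether the diet difference itself differed between families called 0 probes with limma, and 1083 had an unadjusted p under 0.05 against 1029 expected by chance. The lowest adjusted p was 0.662. The median standard error of this difference was 0.415 on the log2 scale, and the simulation recovered 54.5% of probes that differed by 2, so smaller differences were mostly not detectable with these arrays. For DLPD15450_1 the difference was -1.03 ± 1.45 (SE), for DLPD09348_1 -1.39 ± 1.99 (SE) and for DLPD04451_1 -1.25 ± 0.886 (SE), and limma's adjusted p was at least 0.959 for each of these.

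The families were compared over both diets. 7 probes of 5 transcripts passed, 5 higher and 2 lower in family G, and 1983 had an unadjusted p under 0.05. DLPD12671_1 (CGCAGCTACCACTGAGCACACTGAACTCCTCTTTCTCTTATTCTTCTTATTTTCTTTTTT, 38.3% GC) was higher in family G, with a fitted log2 difference of 2.32 ± 0.418 (SE) and a limma adjusted p of 0.0373. It was well above background in 7 of 8 fish of family g on FD and in every other fish. Its partner probe differed by 2.50 with a limma adjusted p of 0.00526, but was well above background in only 1 of 8 and 1 of 6 fish of family g on FD and VD, and in 4 of 5 of family G on each diet. In family g it stood at -3.0 ± 0.485 (SD, n = 8) on FD and -2.13 ± 0.270 (SD, n = 6) on VD. In family G it stood at 0.327 ± 1.55 (SD, n = 5) and 0.108 ± 1.86 (SD, n = 5), and 2 of its 10 fish lay within the range of family g.

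DLPD10644_1 (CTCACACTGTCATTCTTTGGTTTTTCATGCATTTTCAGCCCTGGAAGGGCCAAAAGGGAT, 45% GC) was 2.96-fold lower in family G, with a log2 difference of -1.56 ± 0.256 (SE) and a limma adjusted p of 0.0179, and its partner probe, well above background in all but 1 of 5 fish of family G on VD, differed by -2.35 with a limma adjusted p of 0.00201. It stood at -2.21 ± 0.444 (SD, n = 5) on FD and -2.09 ± 0.826 (SD, n = 5) on VD in family G, and at -0.413 ± 0.311 (SD, n = 8) and -0.756 ± 0.685 (SD, n = 6) in family g. DLPD07649_2 (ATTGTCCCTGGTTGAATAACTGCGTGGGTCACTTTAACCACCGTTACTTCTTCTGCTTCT, 45% GC) was higher in family G, with a fitted log2 difference of 2.56 ± 0.452 (SE) and a limma adjusted p of 0.0373, but its partner probe differed by -0.0857. The partner was well above background in only 2 of 6 and 2 of 8 fish of family g and in 0 of 5 and 1 of 5 of family G on VD and FD, so it neither supports nor opposes the difference. DLPD07649_2 was well above background in 2 of 6 fish of family g on VD, 6 of 8 on FD and 4 of 5 of family G on FD, and no fold is given. It stood at -1.36 ± 2.22 (SD, n = 5) on FD and -1.87 ± 1.42 (SD, n = 5) on VD in family G. In family g it stood at -3.57 ± 0.704 (SD, n = 8) and -3.56 ± 0.729 (SD, n = 6). Without the sex term its difference was 1.95 and the call was lost, with a limma adjusted p of 0.124. Normexp reduced the family differences to 0.725 for DLPD12671_1, -0.597 for DLPD10644_1 and 0.563 for DLPD07649_2. The call was lost in 9 of 17 alternatives for DLPD12671_1, in 5 of 18 for DLPD10644_1 and in 9 of 17 for DLPD07649_2, and in 12, 3 and 10 of 24 fits that left out 1 array. On all 6 slides that held both families, DLPD12671_1 was higher and DLPD10644_1 lower in family G. DLPD07649_2 was also higher on all 6. The 3 probes were picked on the same fish, so this agreement was largely fixed in advance and is no separate support. With slide as a block 0 probes passed. There DLPD12671_1 differed by 2.57 and DLPD10644_1 by -1.61, with limma adjusted p of 0.208 and 0.159.

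**Figure D5:**
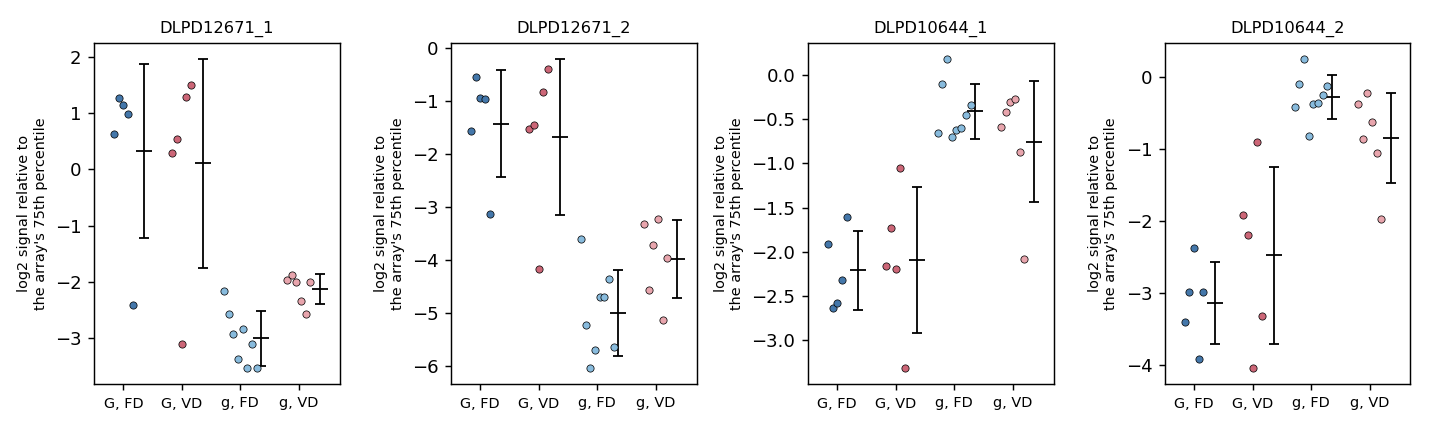
Log2 signal relative to the array's 75th percentile (vertical axis) of both probes of DLPD12671 and of DLPD10644, by family and diet (horizontal axis). Points are single fish and bars give the mean and SD. DLPD12671_1 is higher in 8 of 10 fish of family G than in any fish of family g, and DLPD10644 is lower in family G on average.

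On FD alone, 2 probes passed, namely DLPD12671_2, with a log2 difference of 3.23 and a limma adjusted p of 0.00568, and DLPD10644_2, with -2.94 and a limma adjusted p of 0.00363. DLPD12671_2 was well above background in 1 of 8 fish of family g and 4 of 5 of family G, so its size is uncertain. Both were named after their values were seen. The count was 0 with slide as a block, with the replicate number as a block, with normexp and with the strict filter on dim probes. An unadjusted p under 0.05 was reached by 2402 probes. On VD alone 0 probes passed with limma and 996 had an unadjusted p under 0.05, fewer than the 1029 expected by chance. There DLPD12671_2 differed by 1.77 and DLPD10644_2 by -1.75.

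Females and males differed in 0 probes with limma. An unadjusted p under 0.05 was reached by 1599 probes, and the lowest adjusted p was 0.428, from 7 females and 17 males. The median standard error was 0.245 on the log2 scale.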

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

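The tests of both probes of DLPD12671 and of the fit without 2 fish were chosen only after the result was seen, and the fits with scan day and signal level were added after other results were seen. The fit without 2 fish favours probes on which those fish depart from their family, and the fish were picked by a measured value. In 72 tests of a group's extreme fish, 8 values stood apart from the rest of their group, and chance flags about 1 in 20 such groups.

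DLPD12671_1 had 2 levels in family G: replicate 5 on FD read -2.41, where the others lay between 0.635 and 1.28, and replicate 3 on VD read -3.1, where the others lay between 0.3 and 1.51. All fish of family g lay between -3.53 and -1.88, so that 2 of 10 fish of family G lay inside the range of family g. A sequence difference under a single probe is argued against, since the partner probe, which shares no stretch longer than 6 bases, correlated at 0.985 over the 10 fish and read -3.13 and -4.17 in this pair, neither well above background, against a highest value of -3.24 in family g. Mislabelled fish stay open: a score from 200 other probes placed only 19 of the 24 fish on their own family's side, and of 25 other probes called for family without this pair, 6 and 10 read nearer to family G in replicate 5 on FD and replicate 3 on VD, while DLPD10644_2 (-2.99 and -4.05, the latter not well above background) and DLPD07649_2 (-0.88 and -1.27) lay beyond all fish of family g on the side of family G. A sequence difference that affects both probes, or a variant altering expression that segregates within family G, may also account for the levels, as untested hypotheses.

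The diet difference over both families is weighed next. Slide or scan day as the whole source is argued against, because 3441 probes passed with slide and 3805 with scan day as a block. The test within slides did not decide. Each of the 7 slides with both diets had most called probes in the same direction, but the bound set beforehand was over 75% on each. Slide 8 had 67.3%, and its only fish on VD was replicate 3 of family G. That fish also fell on the other diet's side when held out, so the 2 tests are not separate there. Signal level as the source is argued against by a median ratio of 0.989 between the differences with and without signal level as covariates. A single fish as the source is argued against, since leaving out any 1 fish left at least 3269 probes. That cannot decide whether a few fish together were the source. On this, 2 of 24 held-out fish fell on the other diet's side, where the bound set beforehand was 1, so it stays open. Sources that may differ between the diet groups but are not in the labels could not be weighed. The relation of the diet difference to probe GC content, given below, was not explained. The diet itself stays open as 1 explanation, a hypothesis tested on the same fish.

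The leading component of the differences between fish of a group held 19.8% of that variance. Across probes, the size of its correlation with the diet difference was 0.0827. Of 100 arrangements of diet, the real one included, 79 gave as high a correlation. The other arrangements leave the real diet difference among the differences within groups. They therefore cannot decide whether the component follows the diet difference more closely than chance. Slide may be a source of the component. The share of its variance between slides was 0.763, above the 95th percentile of 0.588 over 10000 permutations (one-sided permutation p = 0.0018). No biological explanation was tested. Replicate 1 of family g on VD scored 2.42, where the others of its group lay between -0.953 and -0.109.

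The remaining values are given without explanation. The same fish, replicate 1 of family g on VD, stood at 68.9 on the second principal component, where the others lay between -63.0 and -14.6. Replicate 4 of family G on FD had a 75th percentile signal of 276, where the others lay between 124 and 162. The root mean square distance from the group was 0.684 for replicate 5 of family G on FD, where the others lay between 0.470 and 0.528, and 0.693 for replicate 2 of family G on VD, where the others lay between 0.521 and 0.568. DLPD10644_1 read -2.08 in replicate 6 of family g on VD, where the others lay between -0.867 and -0.274.

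Other arrangements of the same fish were counted to see how often chance gives as many probes. For diet over both families, 1 of 100 splits gave as many probes as the real 4333, namely the real one, and the highest other gave 251. For diet in family G it was 1 of 100, with 881 against 384, and in family g 1 of 100, with 2255 against 268. These splits, which ignore slide, make chance unlikely for the 3 counts but do not exclude it. The lowest share that 100 splits can give is 1 of 100. In family G the count was also 0 without replicate 1 on FD. With slide as a block the count was 3441 over both families, 935 in family g and 41 in family G. In family G the 4 named probes then missed the threshold, and each difference was smaller. It was 3.84 against 4.49 without the block for DLPD10072_1, and 3.63 against 4.2 for DLPD15450_1. For DLPD09348_1 it was -5.08 against -5.57, and for DLPD04451_1 -3.2 against -3.76. These probes were picked as the largest of the fit without the block and say little about the others. Whether slide is a source of the count in family G was therefore not settled. For family over both diets, 3 of 100 splits gave at least the real 7 and the highest other gave 34, and for family on FD 4 of 100 gave at least 2, with a highest other of 4. These shares are below 0.05, but 8 counts were tested in this way and both counts fell to 0 with slide as a block, although the family differences of DLPD12671_1 and DLPD10644_1 were then 2.57 and -1.61. Both probes were picked on the same fish in the fit without the block, so these sizes are no separate support. The evidence against chance is weak for the counts of family over both diets and family on FD. A split with 34 probes shows that a regrouping can call several times the real count, and what that split follows was not examined. For diet by family, family on VD and sex the real count was 0, which every split reaches, so the splits cannot test chance there. The highest others were 34, 236 and 252.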

How the results depend on the processing

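Alternatives added after the data were seen are slide as a random block, scan day as a block, signal level covariates, normexp with quantile normalization, the second percentile scaling, leaving out slide 9 and, for family only, leaving out 2 fish of family G, which gave 25 probes beside those of DLPD12671. Diet by family and sex stayed at 0 probes in every alternative run, and family on VD in all but 1. With normexp background correction the counts were 35 for diet over both families and 0 for diet in family G, diet in family g, family and family on FD. The leading component then held 75.3% of the variance within groups, against 19.8%, and normexp followed by quantile normalization gave 4317 for diet over both families, 20 for family and 10 for family on FD. With males alone they were 914 for diet, 0 for diet in family G, 11 for family and 4 for family on FD, from 17 fish. The mean per transcript, over 11440 transcripts, gave 2463 for diet, 529 in family G, 1385 in family g and 2 for family. Slide as a block gave 41 in family G, 935 in family g, and 0 for family and family on FD. Scan day as a block gave 1055 in family g and 4 for family, signal level covariates 1104 in family g, and a random slide block 22 for family. Without a filter, over 38070 probes, counts were 82 in family G, 1021 in family g and 4 for family, with a correlation between families of 0.286. The strict filter, over 13519 probes, gave 3 for family, 0 for family on FD and a correlation of 0.722. Without slide 9 the counts were 83 in family G, 0 for family and 4 for family on FD. Only the groups compared gave 85 in family G, and array weights 2150 in family G and 7 for family on FD. Family and family on FD were 13 and 4 after quantile normalization, 17 and 8 in the deposited table, 32 and 7 without the sex term and 14 and 6 with an intensity trend. The cause of these changes was not tested, also where a smaller or larger set of probes or fish was used.

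With the replicate number as a replicate block the counts were 548 in family G and 0 for family on FD; no other count moved by over 1.5 times. The family count was then 6, but 2 of these were among the 7, and DLPD07649_2, DLPD12671_1 and DLPD10644_1 had adjusted p of 0.168, 0.185 and 0.0555. Same-numbered fish of different groups had correlations of deviations between -0.475 and 0.411 (median 0.0239, 31 pairs), so the numbers did not pair them.

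With each array left out, the counts ran from 3269 to 4767 for diet, 0 to 1597 in family G, 834 to 3177 in family g, 2 to 37 for family, 2 to 8 for family on FD and 0 to 2 for family on VD, and the correlation from 0.471 to 0.609. In family G the count was 0, 64 and 458 without replicates 1, 2 and 3 on FD, and 143, 208 and 1597 without replicates 1, 2 and 3 on VD. In family g it was 1487 and 834 without replicates 2 and 6 on VD. For family it lay within 1.5 times of 7 in 5 of 24 cases, and for family on VD it was 2 without replicate 3 of family G on VD. Of 268 values of named probes under other alternatives, 201 stayed past the threshold, 67 did not and 0 changed sign, although normexp made several differences much smaller. Of 360 with an array left out, 308 stayed past it. Gene list shifts were not run. Dim probes had larger errors, with a median SE of 0.304 in the dimmest of 4 sets of probes ranked by level and 0.165 in the brightest.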

Other observations

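The tests in this part were chosen after the values were seen. The transcripts named for diet also varied together between fish on the same diet. For 7 probes (DLPD15450_1, DLPD10402_2, DLPD10372_2 and DLPD10072_1, higher on VD, and DLPD09348_1, DLPD04451_1 and DLPD04152_1, lower on VD), each fish's distance from its own group mean was correlated over the 24 fish. In all 21 pairs the sign followed the diet directions: probes that differed the same way between diets correlated positively, and probes that differed in opposite ways correlated negatively. The size of Pearson's r ran from 0.244 to 0.983, and 13 of 21 pairs had a Benjamini-Hochberg adjusted p under 0.05 in two-sided permutation tests within groups. The distances did not allow for sex, and the permutations ignored sex and slide, so either may contribute to the shared variation. The fitted female minus male difference, not called, was -2.42 ± 1.06 (SE) for DLPD10402_2 and -2.21 ± 1.04 (SE) for DLPD10372_2. DLPD10402_2, DLPD10372_2 and DLPD04451_1 were well above background in all 24 fish; the other probes were not in some fish, and those dim readings enter their correlations.

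DLPD10402_2 and DLPD10372_2 followed each other closely, with Pearson's r of 0.983 (permutation p = 1e-05, adjusted p = 0.00021) and Spearman's rho of 0.972 (permutation p = 1e-05, adjusted p = 0.00021), the smallest p that 100000 permutations can give. Without the 2 fish farthest from the median of DLPD10402_2, r was 0.975. Whether these probes read separate RNAs was not tested, so their pairs with any further probe partly repeat each other in the counts above. DLPD10402_2 and DLPD04451_1 ran opposite, with r of -0.618 (permutation p = 0.00013, adjusted p = 0.000892) and rho of -0.53 (permutation p = 0.00207, adjusted p = 0.00569), and r of -0.563 without the 2 farthest fish. The pair DLPD15450_1 and DLPD04451_1 had the weakest relation, with r of -0.244 (permutation p = 0.286, adjusted p = 0.286) and rho of -0.324 (permutation p = 0.159, adjusted p = 0.159), and r of -0.143 without the 2 farthest.

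In family g on FD, replicates 1, 2 and 3 read -2.87, -2.07 and 0.03 for DLPD10402_2, while the other 5 fish read between 4.18 and 6.37. The same 3 fish read between 5.89 and 6.29 for DLPD04451_1, above all other fish of that group. DLPD15450_1 was not well above background in these 3 fish, and was in the other 5. They lay on 3 different slides. Replicate 1 was the only female of the group. Replicates 2 and 3 were scanned on the same day, as was replicate 8, which was not among the low fish.

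The spread of fish around their group did not separate the diets. The mean root mean square distance was 0.571 ± 0.0702 (SD, n = 5) on VD and 0.539 ± 0.085 (SD, n = 5) on FD in family G (exact permutation p = 0.46, two-sided). It was 0.607 ± 0.0709 (SD, n = 6) and 0.576 ± 0.038 (SD, n = 8) in family g (exact permutation p = 0.347, two-sided).

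Probes higher on VD had a median GC content of 43.3% (2281 probes), those lower on VD 36.7% (2052 probes) and the others 41.7% (16247 probes). Across probes the diet difference correlated with GC content at 0.168 (Pearson) and 0.186 (Spearman), with probes not being independent replicates. The cause was not tested.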
